A study of Ovis aries with 49 samples.

How the data were processed

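The series measured expression from each parental chromosome in fetal sheep (Ovis aries). Western white-faced ewes carried fetuses of 4 Dorset rams and were fed, from gestation day 30, at 100% (control), 60% (restricted) or 140% (overfed) of the energy that the National Research Council recommends. At day 135 brain, kidney and lung were taken from 15 fetuses, 7 control, 4 restricted and 4 overfed, which gave 45 RNA libraries, and blood DNA of the 4 rams was sequenced, so that there were 49 samples.

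The values used were read numbers per parental allele at single-nucleotide polymorphisms (SNPs). Per the labels and the series text, the authors aligned each library to a reference genome and to an alternative genome and averaged the coverage, so the deposited values are estimated counts: 48.7% of the entries are not whole numbers. Per the submitters' processing notes Trimmomatic 0.33, HISAT2 2.0.5, Picard and SAMtools were used, without a stated role. The variant caller and the genome build were not given in the sources used here. Positions are printed as the deposited lists give them, on RefSeq sequences of the 26 autosomes and X, and no position was taken from another build. Gene symbols came from the deposited lists, in which 677 of 7164 genes have a LOC name only.

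The deposited fetal lists were checked for what they had been filtered on. All 39974 entries had a ram homozygous and a fetus heterozygous at the SNP, at least 20.5 reads, and at least 70.02% of the reads on 1 allele. A SNP with balanced reads was therefore not in these lists, and a gene with a listed SNP has by construction unequal reads there. The filter acts on observed reads, so a SNP with balanced expression passes at 21 reads in 7.84% of cases, by the binomial distribution. A share near 50% for a gene can arise only where its SNPs lie on opposite sides. Coverage minima of 10 or 20 reads change nothing in such lists. The ram lists gave, per fetus, the heterozygous SNPs at which the father's base was known, 26554 to 36708 per fetus and 146487 distinct SNPs over all fetuses. Of these, 4.94% to 8.34% per fetus were listed in 1 or more tissues. These lists hold genotypes only and no measured values.

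For each gene and fetus, paternal and maternal reads were summed over the listed SNPs with at least 10 reads. The paternal share in percent was used for description, and the tests used its empirical logit, the natural log of paternal over maternal reads with 0.5 read added to each. Bias by parent of origin was tested per tissue with limma 3.58.1 (R 4.3.3, version 1.17.8 of data.table), as a moderated two-sided test of the mean logit against 0 in genes with values in at least 3 fetuses, with Benjamini-Hochberg adjustment over all genes of the tissue. A gene was called at an adjusted p under 0.05, and called monoallelic if its mean share was in addition at least 90% or at most 10%. Differences between tissues came from 1 limma fit over all 45 libraries, for genes with at least 3 fetuses in both tissues.

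Diet was given to the ewe. Fetuses that share the number in their description were taken as littermates and averaged first, which left 12 units, 4 per diet. One number marks 3 control fetuses and another marks 2. The 4 pairs within these numbers shared 45.4% to 49.7% of their heterozygous SNPs, the 28 other pairs with the same ram 24.2% to 28.2%, and the 73 pairs with different rams 11.8% to 18.1%. The labels speak of 3 sets of twins, which these numbers do not show. Diet contrasts were tested by limma per tissue in genes with at least 2 units in both diets, for the logit share and for coverage, the log2 of the mean reads per listed SNP plus 1. Coverage was scaled per library by the median log2 ratio over widely listed genes. It is the only view of expression level in these lists, and it exists only where the share filter was passed. The difference of a diet contrast between tissues was tested as an interaction in 1 fit.

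There was no reciprocal cross. All rams were Dorset and all ewes white-faced, so parent and base can be separated only where the father carried different bases in different fetuses. Genes were also sorted by whether both the reference and the alternative base had been seen as the paternal base. This was counted over all SNPs of a gene, so the bases can come from different SNPs, also of the same fetus. The sort therefore bears on the reference base. It does not separate the parent from a difference carried by the whole allele. Single SNPs seen both ways round in a tissue were counted by whether the higher allele followed the parent or the base, with 95% Clopper-Pearson intervals. Intervals on read or SNP counts cover counting error only.

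Gene lists, tests, alternatives and the rule for the genes named were fixed before the data were examined. The lists were known paternally and maternally expressed imprinted genes, imprinted domains, the insulin-like growth factor (IGF) axis, energy sensing, DNA and histone methylation, glucocorticoid and lung maturation, histocompatibility genes, and markers of brain, kidney, lung, blood, muscle and endothelium. Named were every imprinted gene tested, at most 10 other autosomal genes per tissue with the most extreme mean share among those called, on 1 side in every fetus, in at least 4 fetuses and with both bases seen, at most 10 called genes per tissue contrast with the largest difference, and per diet contrast the called genes or, with under 3 called, the 3 with the smallest p. Genes named outside this rule are said to be so. A few genes that the rule names are not reported here.

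The 3 tissues come from the same fetuses, so the fetus pairs the libraries. The check was made across genes, which are not independent replicates. The deviations of the libraries of 1 fetus from their tissue means had a median correlation of 0.227 between brain and kidney, 0.315 between brain and lung and 0.296 between kidney and lung, over 15 fetuses each. Libraries of different fetuses had -0.0888, -0.0957 and -0.112. The fit with the fetus as a block is given where it changes a call.

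The tests were tried on simulated data. In simulated bias data 31% to 40% of genes put on 1 side in every fetus were recovered, and 0.313% to 0.708% of genes with random sides were called. For the tissue contrasts a logit shift of 1 was recovered in 51% to 60% of genes and a shift of 2 in 80% to 84%, with 1.86% to 2.64% of unshifted genes called. For diet and share, a shift of 1 was recovered in 32.7% to 61.0% and of 2 in 67.3% to 87.5%. A real SNP whose share moved to balance would mostly leave the lists. The recovery rates for share, between tissues or diets, therefore do not apply to such moves. For diet and coverage, a log2 shift of 1 was recovered in 67.8% to 85.5% and of 2 in 88.9% to 98.7%. The bias simulation gave sides at random and did not model SNPs whose side follows the base. Its low rates of false calls do not apply to such SNPs. It also shuffled the shares over all genes and fetuses, so simulated genes did not keep the spread of a real gene. Its rates therefore do not tell how often genes with a narrow spread, such as some in 3 fetuses, are called by chance.

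Alternatives tried were other read minima, the mean of SNP shares or the deepest SNP in place of sums, other pseudocounts, weights by read number, other minimum numbers of fetuses or units, a test against the median logit, an exact sign-flip permutation test, littermates averaged or kept apart, control fetuses only, the fetus, ram or replicate number in the model, other scalings of coverage, and leaving out each library, fetus or unit. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 served for tables, exact tests and figures. The sequencing runs of single libraries are not given in the labels, so no run could be entered as a batch.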

Results

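Allele-specific expression was measured in brain, kidney and lung of 15 near-term fetuses, 7 from control, 4 from restricted and 4 from overfed ewes. The lists held 694 ± 316 (SD, n = 15) SNPs per brain library, 823 ± 362 per kidney library and 1148 ± 343 per lung library. The reads at these SNPs summed to 10477 to 82301 per brain library, 6530.5 to 71952.5 per kidney library and 31581 to 194732.5 per lung library. The median SNP of a library had 29.8 ± 1.78 reads in brain, 30.97 ± 2.30 in kidney and 34.0 ± 4.16 in lung. A listed SNP has over 70% of its reads on 1 allele, so the lists hold unequal read numbers only, and the paternal share of a single SNP is either below 30% or above 70%. A SNP with balanced expression would pass this filter by counting error in 7.84% of cases at 21 reads and in 2.01% at 32, the median, so some listed SNPs can be balanced. How the fetal genotypes were obtained is not given in the sources used here. Genotypes read from RNA would miss a SNP expressed from 1 allele only, and IGF2, H19, MEST, MEG3, DLK1, PEG10, SGCE and SNRPN had 0 informative fetuses.

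Tissue markers were seen only where a fetus happened to carry a listed SNP. Of 15 kidney markers, 8 were listed in kidney, among them UMOD (uromodulin) in 5 libraries at 392 reads per SNP and AQP2 (the collecting duct water channel) in 1 library at 391. The brain list had 4 of 15 in brain, among them NEFM (a neurofilament) at 189 reads per SNP in 5 libraries. The lung list had 1 of 11 in lung, SLC34A2 (a phosphate transporter of alveolar cells) at 183 reads per SNP in 4 libraries. Some markers were listed in other tissues: MAP2 in 6 lung and 3 kidney libraries at 35.3 and 23.8 reads per SNP, GATM in 2 brain and 2 lung libraries, and AQP1 in 3 lung libraries. Endothelial markers were listed in each tissue, 3 of 4, and no blood or muscle marker was listed in any.

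The first question of the series was which genes are expressed from 1 parental allele. PEG3, a paternally expressed zinc finger gene, was paternal in all 3 tissues. Its paternal share was 85.8% ± 5.06 (SD, n = 8) in brain, 87.0% ± 1.956 (n = 14) in kidney and 85.7% ± 3.96 (n = 14) in lung, with adjusted p of 1.25e-05, 3.75e-12 and 5.15e-10. INPP5F, an inositol phosphatase with a paternally expressed brain transcript, was almost wholly paternal in brain, at 97.6% ± 0.718 (n = 7, adjusted p = 8.58e-08). IGF2R, the receptor that clears IGF2, was maternal, with paternal shares of 12.2% ± 4.43 (n = 4) in kidney and 6.37% ± 2.58 (n = 4) in lung. GRB10, an adaptor that restrains insulin and IGF signalling, was maternal at 20.6% ± 3.64 (n = 15, adjusted p = 9.62e-11) in lung and 24.2% ± 5.98 (n = 7, adjusted p = 2.09e-04) in kidney.

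For INPP5F, IGF2R and GRB10 the father carried the reference base at some SNPs and fetuses and the alternative base at others, and the direction was the same. In lung GRB10 the mean paternal share was 20.4% in 10 fetuses with a paternal reference base and 20.48% in 12 with a paternal alternative base. Only 15 fetuses had values, so some held both bases at different SNPs of the gene. These counts do not separate the parent from a difference carried by the whole allele. The 18 lung SNPs of GRB10 lay on chromosome 4 between 5234736 and 5265632. Those of IGF2R lay on chromosome 8 between 82850981 and 82872821, and those of INPP5F on chromosome 22 between 38839760 and 38841513. PEG3, on chromosome 14 between 60912163 and 60913558, had the reference base on the paternal allele at every entry, so its parent and base were not separable. Whether the SNPs lie in exons or introns was not analysed here.

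Other maternal list genes were COPG2, a coat protein gene beside MEST, at 15.9% ± 5.27 (n = 8) in brain and 25.2% ± 4.18 (n = 3) in kidney, and in kidney PPP1R9A at 23.3% ± 2.69 (n = 9), PHACTR2 at 27.2% ± 1.67 (n = 5) and GATM at 27.4% ± 2.55 (n = 3). IMPACT was paternal in kidney at 73.9% ± 2.03 (n = 3) and was not called in lung (62.2% ± 36.6, n = 3, adjusted p = 0.600). Its kidney call had only paternal reference bases, and in lung it was at 83.3% with a paternal reference base (2 fetuses) and at 20% with the alternative base (1 fetus). The kidney calls of COPG2 and GATM had only paternal alternative bases. PON3, a paraoxonase placed in the maternal list, was paternal in lung at 74.8% ± 2.10 (n = 6, adjusted p = 3.85e-05), always with the alternative base on the paternal allele. ZFAT was not called in brain (42.7% ± 28.0, n = 3) or lung (30.3% ± 10.7, n = 3, adjusted p = 0.0603). Tested against the median logit of all genes in place of 0, the kidney calls of GRB10 (adjusted p = 0.145), COPG2 (0.450), PHACTR2 (0.437) and GATM (0.6246) were lost. That median stood at a paternal share of 28.6%. The means cover listed fetuses only. Informative fetuses, listed or not, were 15 for GRB10 and ZFAT, 14 for PEG3, COPG2 and PPP1R9A, 13 for PHACTR2 and IMPACT, 10 for INPP5F and GATM, 9 for PON3 and 4 for IGF2R. For the unlisted ones the lists do not tell a balanced share from too few reads.

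**Figure D1:**
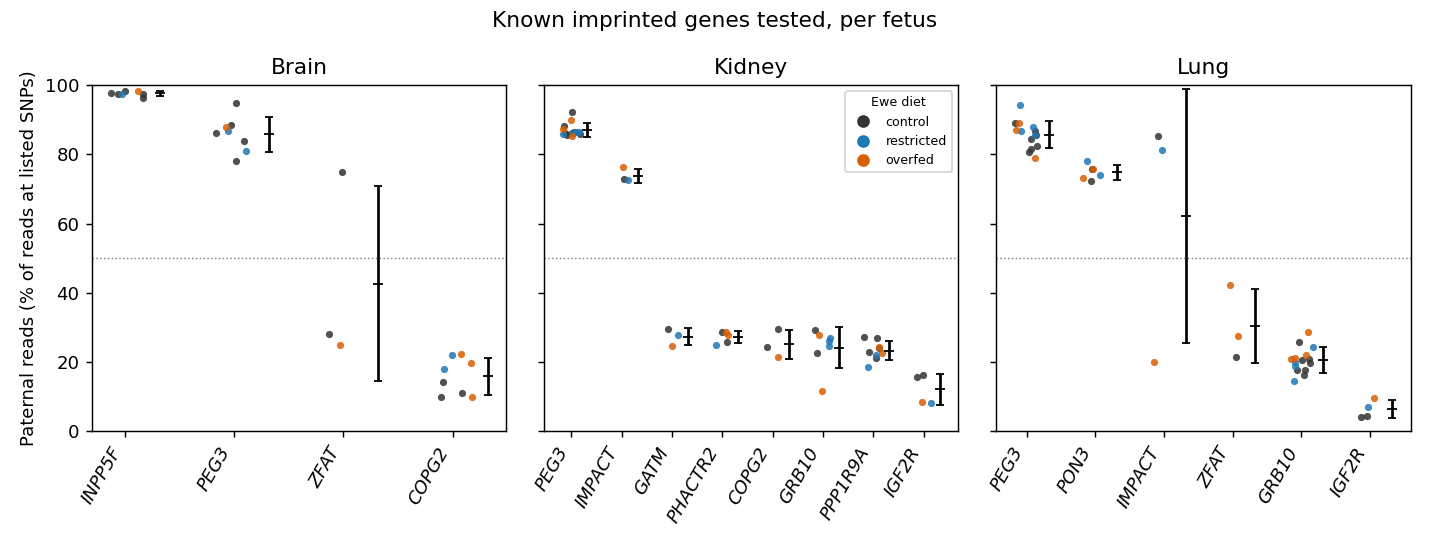
Paternal share of reads (percent, vertical axis) of each known imprinted gene tested in brain, kidney and lung. Each point is 1 fetus, coloured by the diet of the ewe, and bars give the mean and SD over fetuses. INPP5F in brain sits at 97.6% and PEG3 at 85.7% to 87.0%, while IGF2R, GRB10 and COPG2 sit below 30% in every fetus.

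Of the 94 list members, 51 had a SNP at which at least 1 fetus was informative and 31 were listed. Autosomal members tested were 4 in brain, 8 in kidney and 6 in lung, of which 3, 8 and 4 were called over all genes and 3, 8 and 5 adjusted over the list alone. Among other autosomal genes 527 of 819, 646 of 993 and 866 of 1405 were called, and the difference between the list and these genes did not pass Fisher's exact test, two-sided, in brain (p = 1), kidney (p = 0.0563) or lung (p = 1). Among genes with both bases seen as the paternal base, calls on 1 side in every fetus were made for 4 of 4 members in kidney against 144 of 372 other genes (Fisher's exact p = 0.0234), 2 of 3 against 109 of 305 in brain (p = 0.295) and 2 of 4 against 171 of 552 in lung (p = 0.592). Including genes in 1 or 2 fetuses, autosomal maternal list members lay on the maternal side by mean share in 9 of 10 cases in brain, 15 of 19 in kidney and 10 of 14 in lung. Autosomal paternal list members lay on the paternal side in 4 of 5, 6 of 7 and 4 of 5. MCTS1, a paternal list gene on X that is not in these counts, was at 16% in 1 brain and 13.9% in 1 lung. Some means join 1 fetus on each side: PHACTR2 in brain (23.8% and 75%), SLC22A2 in kidney (27.5% and 71.95%) and TRAPPC9 in kidney (28.6% and 70.2%). Cases on the other side included BLCAP (79.5%, 79.7% and 84.8%, listed in 1 of 11 informative fetuses per tissue), TFPI2, TSSC4 and WRB (21.3%, 23.3% and 28.3%, 2 fetuses per tissue).

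The domain lists gave the same genes. COPG2 was the 1 member of the MEST domain tested in brain and kidney. The PEG10/SGCE domain had PPP1R9A tested in kidney and PON3 in lung, the IGF2R domain had IGF2R in kidney and lung, and the PEG3 domain had PEG3 in all tissues, and each was called. No member of the DLK1/MEG3, IGF2/H19 and KCNQ1, SNRPN or GNAS domains had values in 3 fetuses. Listed from fewer fetuses were BEGAIN (paternal share 100% in 2 kidneys), PHLDA2 (26.4% in 1 kidney), SLC22A18 (23.5% in 2 kidneys), KCNQ1 (19.5% in 1 kidney and 18.9% in 1 lung) and UBE3A (29.6% in 1 lung). CARS (74.4% in 1 kidney and 72.1% in 2 lungs) and TSSC4 (73.1% in 1 lung), of the KCNQ1 domain, lay on the paternal side.

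In the IGF and growth list, 3 of 19 members were tested in kidney and 3 in lung, and all were called maternal: IGF2R, GRB10 and IGF1R, the IGF1 receptor. IGF1R had a paternal share of 17.9% ± 4.81 (n = 11) in kidney and 26.7% ± 19.1 (n = 12) in lung, with the reference base always paternal and a SNP heterozygous in 12 of the 15 fetuses. In the methylation list MAT2A, which makes the methyl donor S-adenosylmethionine, was called maternal in brain (12.3% ± 2.78, n = 8), kidney (10.2% ± 1.35, n = 8) and lung (16.2% ± 2.33, n = 8), from the single SNP 57090279 on chromosome 3 with a paternal reference base. DNMT3A (20.3% ± 4.64, n = 7), a DNA methyltransferase, and EZH2 (16.1% ± 5.67, n = 6), a histone methyltransferase, were called maternal in lung, also with paternal reference bases only. The list thus had 1 of 2, 1 of 2 and 3 of 4 tested members called in brain, kidney and lung, and these counts were equal when adjusted over the list alone. Of the energy sensing list, FOXO1 in brain and TSC2 in kidney were not called and TSC2, an inhibitor of mTOR signalling, was called in lung (14.2% ± 3.64, n = 4). The lung call of TSC2 had paternal reference bases only. No glucocorticoid or lung maturation gene was tested. Among histocompatibility genes, OLA-I was called paternal in brain (87.5% ± 7.99, n = 10), kidney (80.6% ± 17.8, n = 10) and lung (75.5% ± 15.6, n = 12), and OVAR-DRB3 maternal in lung (21.4% ± 4.78, n = 3). Only 1 base had been seen as paternal for OLA-I in brain and for OVAR-DRB3 in lung. In kidney and lung OLA-I did not keep to 1 side in every fetus.

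Over all genes, 565 of 863 tested were called in brain, 691 of 1047 in kidney and 899 of 1476 in lung. Maternal calls were more numerous than paternal ones: 385 against 180, 461 against 230, and 578 against 321. In autosomal genes with both bases seen as the paternal base the counts were closer, with 60 maternal against 60 paternal calls in brain, 86 against 78 in kidney and 105 against 103 in lung. Monoallelic were 61 genes in brain (17 paternal, 44 maternal), 23 in kidney (20 paternal, 3 maternal) and 34 in lung (23 paternal, 11 maternal). With both bases seen these were 3 (3 paternal, 0 maternal), 1 (1 paternal, 0 maternal) and 2 (0 paternal, 2 maternal). The paternal excess in kidney and lung was not kept at a threshold of 80% or 20%, with 78 paternal and 235 maternal genes in brain, 89 and 192 in kidney, and 109 and 180 in lung. Examples, chosen after their values were seen, are TMEM59 (94.4% ± 2.86, n = 11, in brain) and RPL9 (95.5% ± 2.54, n = 15, in lung) on the paternal side and, on the maternal side, RAB1A (4.49% ± 0.654, n = 7) and GPI (6.03% ± 2.94, n = 14) in brain and RNF19A in lung (0.938% ± 1.43, n = 6). Of these, RPL9, RAB1A and GPI had only 1 base seen as the paternal base, so parent and base were not separable. By an exact sign-flip permutation test in genes with 6 or more fetuses, 227 of 280, 263 of 336 and 402 of 532 were called. Of the 384 autosomal genes tested in all tissues, 233 were called in all 3, and 230 of these lay on the same side, 57 paternal and 173 maternal.

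These calls depended on the base. Of autosomal genes in which only 1 base had been seen as the paternal base, 79.6% were called in brain, 78.4% in kidney and 77.4% in lung, against 39.0%, 43.6% and 37.4% of genes with both. Paternal calls had mostly a paternal reference base in 79.5%, 76.4% and 80.4% of genes and maternal calls in 89.1%, 87.1% and 88.0% (Fisher's exact p = 0.00457, 0.000765 and 0.00367, two-sided). Among gene and fetus pairs with several listed SNPs, 15.0%, 15.98% and 17.8% held SNPs on opposite sides. Both bases had been paternal at 246 cases of an autosomal SNP and tissue, from 192 distinct SNPs. In these the higher allele followed the base in 224 (91.1%, 95% Clopper-Pearson interval 86.8% to 94.3%, with all cases taken as independent) and the parent in 22. Those that followed the parent, chosen after their values were seen, included CAPN5 in lung, at 2 SNPs with paternal shares of 24.7% to 28.8%, 1 SNP of SERPINB1 in kidney and another in lung (25.9% to 28.8%), and MLKL in lung (80.95% and 85.2%). The other SERPINB1 SNPs seen both ways round followed the base. Without the SNPs heterozygous in 10 or more fetuses, a setting chosen after the data were seen, 318 of 561, 393 of 667 and 526 of 991 genes were called.

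**Figure D2:**
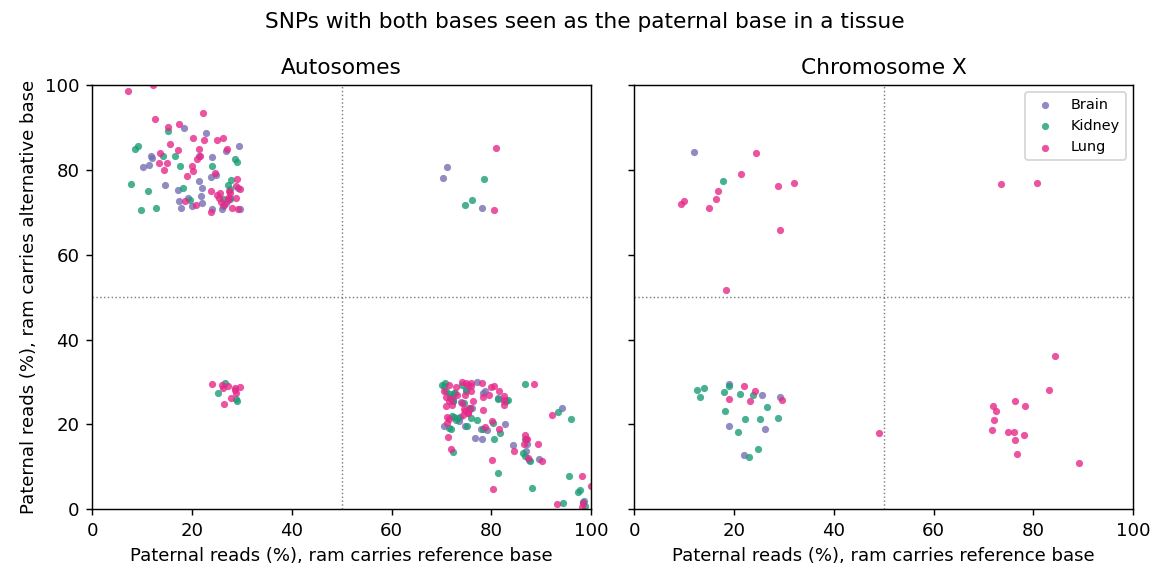
Mean paternal share (percent) of SNPs in fetuses whose father carried the reference base (horizontal axis) against fetuses whose father carried the alternative base (vertical axis). Each point is 1 SNP in 1 tissue. Points at upper left and lower right follow the base, which holds for 224 of 246 autosomal cases, and points at lower left and upper right follow the parent.

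Genes outside the list that held their side with both bases included OAS1, an interferon-induced antiviral enzyme, which was paternal at 83.9% ± 5.33 (n = 5) in brain, 85.5% ± 8.09 (n = 8) in kidney and 89.6% ± 3.52 (n = 11, adjusted p = 1.33e-08) in lung. Its lung SNPs lay on chromosome 17 between 61043955 and 61045118, and the paternal share was 91.0% with a paternal reference base and 85.6% with the alternative base, 7 fetuses each. LOC101116226 on chromosome 4 (106429540 to 106434588) was paternal at 88.5% ± 6.05 (n = 11), 90.7% ± 4.31 (n = 13) and 89.3% ± 5.22 (n = 14). LOC101105348 on chromosome 13 was maternal at 20.2% ± 6.01, 19.04% ± 5.89 and 12.5% ± 4.42 (n = 15 each). LOC105612165 on chromosome 6 was maternal in brain (15.5% ± 3.10, n = 7) and kidney (12.96% ± 4.02, n = 7), and DNM2, a dynamin of membrane fission, in kidney (14.4% ± 7.77, n = 8) and lung (13.9% ± 7.36, n = 7). In all, 10 genes were called on 1 side in every fetus and in all 3 tissues with both bases seen in each, 9 paternal and 1 maternal. The bases came in part from different SNPs of the same fetuses. LOC101105348 in lung had a paternal reference base in 15 fetuses and the alternative base in 9, of 15 fetuses. Such genes are therefore not shown to be biased by parent of origin. Beyond OAS1, LOC101116226 and LOC101105348 they were, chosen by this count after the data were seen, ADSSL1, AHNAK, ARV1, LOC105616533, PARG, TTC21B and ZBTB8OS.

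Most further genes named by the rule rested mainly on 1 base. RAB14 in brain was maternal at 13.9% ± 7.19 (n = 15) and at 73.7% in the 1 fetus with a paternal alternative base. LOC105602840 in brain was paternal at 89.2% ± 15.7 (n = 5) and at 28.1% at the paternal alternative base of 1 fetus. Kept on their side with the other base were, in brain, AIF1L (93.8% ± 8.48, n = 4), DENND5A, TLN2 and MRPL13, in kidney ARID1A (89.2% ± 6.45, n = 6), LOC101109636 (11.04% ± 4.07, n = 8), HSPA1A (88.6% ± 4.07, n = 9), TFF1 and CRELD1, and in lung PTPRB, LOC101112168, LTBP2, CRELD1, RIN3 and ARV1. The rule already required 1 side in every fetus. The alternative base was paternal in 1 fetus only, near the filter limit, in AIF1L (70.6%), MRPL13 (73.2%), HSPA1A (72.1%), PTPRB (72.7%) and ARID1A (75.3%). Such a fetus does not separate parent from base, nor do bases seen at different SNPs of a gene. TFF1 had 15.3% in 1 fetus, LOC101109636 10.3% in 5 and LOC101112168 17.6% in 3. LTBP2, a matrix protein that binds latent TGF-beta family proteins, was at 85.02% ± 3.73 (n = 14) and lost its call without the SNPs heterozygous in 10 or more fetuses (adjusted p = 0.803).

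On chromosome X, 35 of 40 genes tested were called in brain, 37 of 46 in kidney and 29 of 65 in lung. USP11, a deubiquitinase, was maternal at 7.24% ± 5.26 (n = 14) in brain and 18.1% ± 4.45 (n = 12) in kidney, and EIF2S3, a translation initiation factor, was paternal at 88.6% ± 1.70 (n = 6), 85.05% ± 4.97 (n = 7) and 90.4% ± 2.24 (n = 8) in brain, kidney and lung. EIF2S3 was listed only in the 8 fetuses whose X entries lay mostly in genes that have a copy on Y, so its side is not evidence on the parent of origin. Of the USP11 fetuses, 8 of 14 in brain and 6 of 12 in kidney belonged to this group, and the same limit holds for them. The X counts pool this group with the other fetuses, and fetal sex was not entered in any test. These X genes were chosen after their values were seen. At X SNPs with both bases seen as paternal, 6 of 7 cases in brain and 15 of 16 in kidney were maternal with either base, and 24 of 33 in lung followed the base. Most of these cases set 1 fetus against 1 other, and some genes gave several SNPs. Whole lung libraries differed in side. Their median paternal share on X was 74.3% in overfed fetus 2 and 76.1% in restricted fetus 2. It was 24% in overfed fetus 3 and 18.9% in overfed fetus 4. These counts therefore do not separate the base from the side of a whole library.

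The reference base was followed as a view on mapping bias, which it does not measure alone, since it was mostly the paternal base. At SNPs heterozygous in all 15 fetuses it was paternal at 98.6%, 98.5% and 99.6% of entries in brain, kidney and lung. The reference base was the higher allele at 43.8% ± 2.71 of SNPs per brain library, 46.4% ± 2.38 per kidney library and 46.0% ± 2.54 per lung library (SD, n = 15). The median reference share per library was 28.8% ± 0.600, 31.99% ± 10.7 and 34.6% ± 14.4. Since no SNP lies between 30% and 70%, this median takes 1 of 2 levels, near 29% or near 70%, and the share of summed reads was 45.1% ± 2.52, 48.7% ± 2.91 and 48.7% ± 3.15.

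The second comparison asked whether the paternal share differs between tissues of the same fetuses. ATP6V0D1, a subunit of the vacuolar proton pump, was maternal in brain (1.42% ± 2.43, n = 11) and lung (3.23% ± 3.24, n = 6) and paternal in kidney (82.4% ± 6.69, n = 9), but its kidney and lung values came from different SNPs. PPP3CB, a catalytic subunit of calcineurin, was maternal in brain (3.38% ± 1.94, n = 12) and paternal in kidney (75.5% ± 5.61, n = 5). TUBB6, a beta tubulin, was at 47.9% ± 34.0 (n = 15) in brain and at 98.1% in kidney (SD 3.39, n = 12) and lung (SD 4.79, n = 15), and lost both calls with precision weights (adjusted p = 0.145 and 0.146). Between brain and kidney 54 of 465 genes were called, 9 higher and 45 lower in brain. Between brain and lung 77 of 512 were called, 16 higher and 61 lower. Between kidney and lung 3 of 738 were called, all higher in kidney: ATP6V0D1, LOC101108092 and CDCA7L. With precision weights the last comparison had 11 calls, 4 higher and 7 lower in kidney.

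Most genes called against brain lay on the same side in both tissues. For 44 of the 54 and 62 of the 77 both means were on 1 side of 50%, and in 38 and 52 of these the brain mean was the farther from 50%. RAB1A, a small GTPase of vesicle transport, chosen after its values were seen, was at 4.49% ± 0.654 in brain against 14.8% ± 4.26 in kidney and 20.96% ± 2.39 in lung (n = 7 each). LOC105609801 was at 1.49% ± 0.856 (n = 5) in brain and 24.1% ± 3.98 (n = 4) in lung, at the single SNP 27818832 of chromosome 8. KCNIP2, which modulates potassium channels, was paternal at 83.1% ± 7.06 (n = 8) in brain and 100% in 3 kidneys, 2 of them at SNP 21702472, which was not listed in brain. Opposite sides were seen in 10, 15 and 3 called genes. In G3BP2, a stress granule protein, the SNP 90060978 on chromosome 6 stood at 75.4% ± 2.03 in 3 brains, 7.44% ± 5.16 in 5 kidneys and 7.39% ± 4.44 in 7 lungs. COG3, a subunit of a Golgi tethering complex, was paternal in brain (77.8% ± 11.2, n = 3) and maternal in kidney (25.9% ± 5.48, n = 3) and lung (22.8% ± 4.95, n = 10).

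**Figure D3:**
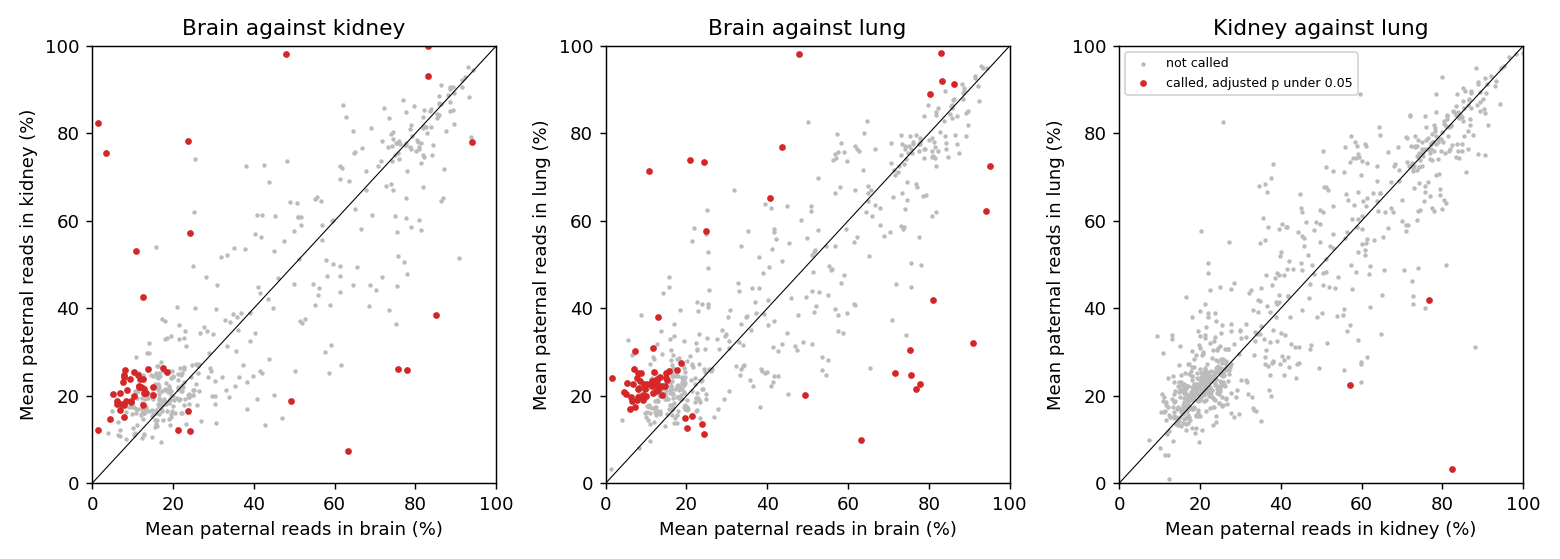
Mean paternal share (percent) of each gene tested in both tissues of a pair, 1 tissue on each axis. Each point is 1 gene, coloured by whether limma called the difference, and the line marks equal shares. Called genes number 54, 77 and 3, and many of those against brain lie at shares below 15% in brain and near 20% in kidney or lung.

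Several of the largest differences rested on SNPs carried by most fetuses, others such as KIAA1644 and DNASE1L1 on SNPs heterozygous in 1 to 9. Against lung, KIAA1644 and DNASE1L1 lost their calls with precision weights (adjusted p = 0.125 and 0.170) and in the fit without SNPs heterozygous in 10 or more fetuses (0.118 and 0.0936), and KIAA1644 also with the deepest SNP (0.0549) and a pseudocount of 2 (0.0539). The fit without SNPs heterozygous in 10 or more fetuses removes none of the SNPs of these 2 genes. Its lost calls do not show that widely carried SNPs made their differences. Heterozygous fetuses numbered 15 for the SNP of COG3, 14 for the G3BP2 SNP and for SNP 34300831 of ATP6V0D1, and 13 for SNP 29209357 of PPP3CB. LOC101120505 (75.7% ± 3.54, n = 5, in brain and 26.03% ± 2.44, n = 8, in kidney), LOC105601865 and LOC101105123 likewise had SNPs heterozygous in 14 or 15 fetuses. Without SNPs heterozygous in 10 or more fetuses 8 of 251, 12 of 291 and 1 of 408 genes were called, including in both brain comparisons TUBB6, LOC105609801, RAB1A, PSMD2, MRPL9 and AGRN. Of the 54, 77 and 3 called genes, 13, 24 and 1 could still be tested without these SNPs, and 8, 11 and 1 of them were still called. TUBB6 rested on SNPs on both sides within brain: SNP 43122275 of chromosome 23 was at 20.1% ± 6.45 in 9 brains against 98.5% ± 1.84 in 7 kidneys, and SNP 43122445 at 92.4% ± 0.882 in 5 brains. Some differences came from different SNPs in the tissues. NRBP1 (24.2% ± 10.5, n = 12, in brain and 73.4% ± 17.7, n = 11, in lung) lost its call when only SNPs listed in both tissues of a fetus were used (adjusted p = 0.917), as did LOC101108092 between kidney and lung (0.0921). ATP6V0D1 had only SNP 34300831 in kidney (82.4%, 9 fetuses) and only SNP 34308750 in lung (3.23%, 6 fetuses), while brain had both (3.15% and 0.105%, 6 fetuses each). CDCA7L had 3 SNPs in kidney, 1 fetus each, of which only 30666440 was also listed in lung. KIAA1644, PARM1, LOC106990101 and the X-linked DNASE1L1, also named by the rule, had mostly or partly different SNPs in the tissues compared.

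With the fetus as a block, 46 of 441, 70 of 474 and 3 of 666 genes were called, 39, 58 and 2 of them shared with the fit without it, and CDCA7L was lost (adjusted p = 0.235 with the block). No known imprinted gene was called between tissues in the limma fit, of 2, 2 and 4 tested. At an unadjusted p under 0.05 there were 2 such results: COPG2 (15.9% in brain and 25.2% in kidney, adjusted p = 0.154) and IGF2R (12.2% in kidney and 6.37% in lung, adjusted p = 0.735). Adjusted over the list alone, COPG2 was called as the only maternal list gene tested between brain and kidney, and IGF2R as the only gene of its domain tested between kidney and lung. PEG3 had means of 85.8%, 87.0% and 85.7%, GRB10 24.2% in kidney and 20.6% in lung (adjusted p = 0.837), IMPACT 73.9% in kidney and 62.2% in lung (0.935), and ZFAT 42.7% in brain and 30.3% in lung (0.678). A gene that is biased in 1 tissue and balanced in another leaves the lists in the latter and could not be tested. INPP5F, at 97.6% in 7 brains, was listed in 1 kidney only (70.3%), of 10 informative fetuses, and was not tested between tissues. MAT2A was not called between tissues over all genes (adjusted p = 0.104 for brain and lung), and was called adjusted over the list alone between brain and lung and between kidney and lung. GRB10, IGF1R and IGF2R, the 3 growth list genes tested between kidney and lung, gave no call over all genes or adjusted over the list alone.

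The third comparison asked whether the diet of the ewe changed the paternal share. The rams were not balanced over the diets. Control fetuses came from rams 3 and 4 only, restricted fetuses from rams 1, 2, 3 and 4, and overfed fetuses from rams 1, 3 and 4. A difference between diets can therefore not be fully told apart from one between rams. GRB10 in lung was at 20.7% in control, 19.5% in restricted and 23.2% in overfed fetuses (4 units each, shares converted from mean logits), and the 95% interval of the logit difference was -0.473 to 0.318 for restricted against control and -0.254 to 0.548 for overfed against control. PEG3 in kidney was at 86.8% in control, 86.1% in restricted and 87.6% in overfed fetuses, with intervals of -0.363 to 0.248 and -0.245 to 0.389. In lung PEG3 was at 84.7%, 88.7% and 84.9%, and in brain at 84.3% in control and 83.4% in restricted fetuses. GRB10 in kidney was at 26.2% in restricted and 19.4% in overfed fetuses. PPP1R9A in kidney was at 24.9%, 20.4% and 24.1%, and COPG2 in brain at 12.0%, 20.4% and 17.1%. PHACTR2 in kidney (27.7% in control, 28.6% in overfed) and PON3 in lung (76.1% in restricted, 74.4% in overfed) could be set against 1 other diet each. The limma test called 0 imprinted genes in any of the 9 comparisons, over all genes or adjusted over the list alone, with the lowest unadjusted p at 0.155 (COPG2). A gene that turns balanced under a diet, imprinted or not, mostly leaves the lists there. Such a loss of bias could then not be tested, and the lack of calls does not speak to it. Some intervals were wide, so differences are not ruled out: that of the logit difference was -0.313 to 1.57 for COPG2 in brain and -0.221 to 0.909 for PEG3 in lung (restricted minus control), and -1.25 to 0.479 for GRB10 in kidney (overfed minus restricted).

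Over all genes the limma test called 0 genes in 8 of the 9 comparisons of share. Genes with an unadjusted p under 0.05 in brain numbered 4 of 196 (restricted minus control), 8 of 260 (overfed minus control) and 6 of 162 (overfed minus restricted). In kidney they were 10 of 304, 16 of 243 and 6 of 180, and in lung 12 of 388, 12 of 476 and 15 of 347. The 1 gene called was GOLGA3, a Golgi matrix protein, in lung for restricted minus control (96.7% in restricted against 16.5% in control, 3 units each, logit difference 4.99, adjusted p = 0.0392). The diets did not list a common SNP of GOLGA3. Restricted fetuses had SNP 44020373 of chromosome 17 at 97.2%, and control fetuses had 4 other SNPs from 43983874 to 44018321 at 9.88% to 26.7%. In overfed lungs both were seen, 96.1% at 44020373 and 23.96% at 44008446. In kidney GOLGA3 was at 97.4% in restricted and 16.3% in control units (2 units each, adjusted p = 0.0913). The lung call was lost without control replicate 1 (adjusted p = 0.171), 2 (0.109) or 4 (0.211), without restricted replicate 2 (0.178) or 3 (0.199), with the ram as a covariate (0.484), and in the deepest SNP alone (0.525). The logit difference of GOLGA3 in these was 4.91, 5.27, 4.78, 4.76, 4.72, 4.68 and 5.001, in the same order.

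Other genes with the smallest p did not pass. In brain KIF5C, a kinesin of neurons, was at 70.8% in restricted, 27.1% in control and 24.99% in overfed units (adjusted p = 0.130 and 0.156, 2 units each), and LOC105614340 at 78.6% in restricted and 22.5% in control units (0.130). KIF5C was called with precision weights (adjusted p = 0.0134 and, for overfed minus restricted, 0.00350) and, for overfed minus restricted, with 40 reads (0.0216), and LOC105614340 with each fetus as a value (0.0454). In kidney APEH was at 70.2% in overfed and 17.5% in control units (0.195). In lung PYROXD2 was at 76.4% in overfed and 18.9% in control units (0.345), and LOC101108865 at 58.2% in overfed, 91.1% in control and 90.8% in restricted units. In the same way PSMD12, BBS4, PPP1R15B, MFF and FBXO18 were named in brain, CSRNP2, NRP2, ZDHHC1, MSRB3, NRBP1 and STAT5B in kidney, and PLCG1, WDR26, PODXL and LTA4H in lung, none of them called. Of the 27 cases named by the rule in 22 genes, 10 compared diets that had no SNP in common, among them KIF5C, LOC105614340, CSRNP2, NRP2, APEH, MSRB3 and PYROXD2. The IGF and methylation lists gave 0 limma calls in any tissue and diet contrast, of at most 2 members tested, and no energy sensing gene was tested. The difference of a diet contrast between tissues gave 0 limma calls in 83 to 205 genes per comparison, with 3 to 9 genes at an unadjusted p under 0.05.

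For coverage at listed SNPs, limma called 0 genes in all 9 diet comparisons. Genes with an unadjusted p under 0.05 numbered 11, 7 and 9 in brain (restricted minus control, overfed minus control, overfed minus restricted), 17, 16 and 4 in kidney, and 13, 23 and 17 in lung. EDNRA, the endothelin receptor type A, had the smallest p in lung: its log2 coverage was lower in overfed than in control units by a difference of -0.70 (SE 0.14, adjusted p = 0.225, 4 units each) and than in restricted units by -0.74 (SE 0.17, adjusted p = 0.275, 4 and 3 units). GRB10 in lung had a log2 difference of 0.59 (SE 0.19, 4 units each) for restricted minus control, with an adjusted p of 0.849 over all genes. It was the 1 imprinted gene, and the 1 gene of the IGF list, that was called adjusted over the list alone. PEG3 in kidney had a log2 difference of 0.79 (SE 0.35) for restricted minus control, with an adjusted p of 0.773. POFUT2 in kidney (-0.80, SE 0.21) for overfed minus control had an adjusted p of 0.357, and GIT1 in brain (1.10, SE 0.30) for restricted minus control one of 0.600. These sizes depended on the scaling: without it EDNRA was at -0.36 and -0.28, POFUT2 at -1.40 and GIT1 at 0.34, and with scaling by total coverage they were -1.01 and -1.18, -0.52 and 1.45. The -1.18 of EDNRA was then called (adjusted p = 0.0256). Also named, and not called, were LOC101116226, EXOSC10, FAM168B, NETO2, ME3, ARHGAP21 and ARV1 in brain, DNASE1, EEF1A1, LTBP3, APEH, DHX57, APOE, SAFB and ADGRG1 in kidney, and ARRB1, MFF, ZFX, ZC3HAV1L, EBP and GRP in lung. The methylation list gave 0 limma calls and no energy sensing gene was tested. The interaction of diet and tissue in coverage gave 0 limma calls in any comparison, with 1 to 11 genes at an unadjusted p under 0.05.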

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

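The tests of explanations for the 3 patterns below were all chosen after the result had been seen. The regroupings of samples and the search for single values far from their group were set out earlier.

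In 64 groups of 4 to 10 libraries or fetuses, 8 single values stood far from the rest of their group, where chance alone gives about 1 in 20. GRB10 in the lung of overfed fetus 3 had a paternal share of 28.6% against 20.9% to 21.9% in the other overfed lungs. PEG3 in the kidney of control fetus 1 was at 92.3% against 85.6% to 88.3% in the other control kidneys. In the brain of control fetus 4, 17.3% of the SNPs had at least 90% of their reads on 1 allele, against 10.7% to 13.3% in the other control brains, and in the lung of control fetus 1 it was 4.39% against 6.84% to 8.03%. The median reads per SNP in the kidney of control fetus 1 were 27.5 against 31 to 32. The median reference share was 70.6% in the kidney of overfed fetus 3 (others 29.1% to 29.8%), 70.1% in the lung of overfed fetus 4 (29.2% to 29.7%) and 70.2% in the lung of restricted fetus 4 (28.9% to 29.2%). These last 3 medians take 1 of 2 levels only, so the rate of 1 in 20 does not apply to them.

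The first pattern concerns SNPs carried by most fetuses: one heterozygous in 1 fetus was listed in 4.24% of cases, one heterozygous in all 15 fetuses in 38.1%, and the paternal base was the higher one at 19.6%, 32.004% and 33.9% of the entries of the latter in brain, kidney and lung. RNA editing is argued against as the whole cause, since the paternal A or T with G or C as the other base made up 34.6% (95% interval 32.5% to 36.8%) of listed SNPs heterozygous in 10 to 14 fetuses and 8.36% (5.58% to 11.9%) of those heterozygous in all 15. Breed differences in sequence are argued against for the SNPs in all 15 fetuses, with 56.04% transversions against 22.9% at SNPs in 1 to 3 fetuses. They are left undecided for those in 10 to 14, with 29.9%, a gap within the bound of 10 points set for this test. Counted per listed SNP and fetus, transversions were 38.6% there against 23.8%. This group is also mixed: SNPs in 10 fetuses were listed in 7.59% of cases and those in 14 in 22.1%. Depth is argued against for those in all 15, which were the listed member of 82.4% (67.1% to 95.1%) of 74 unequal pairs of neighbours within 75 bases, and is left undecided for 10 to 14 (50.3%, 39.4% to 60.6%, 193 pairs). Reads misplaced at exon joins or between near-identical copies were not tested and stay open.

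The second pattern is that more genes were lower than higher in brain in the paternal share, such as RAB1A and PPP3CB. SNPs heterozygous in 10 or more fetuses are left undecided between brain and kidney, where without them 87.5% of 8 called genes (95% interval 47.3% to 99.7%), and 100% of 4 (39.8% to 100%) from SNPs listed in both tissues, were lower in brain. Between brain and lung, 78.9% of 19 called genes (54.4% to 93.9%) from SNPs listed in both tissues were lower in brain without them, and 75% of 12 (42.8% to 94.5%) from all SNPs. Over all autosomal entries without these SNPs, the paternal base was the higher one at 49.6% in brain, 47.6% in kidney and 49.8% in lung. These SNPs are thus left undecided between brain and lung too. Different SNPs in the tissues are argued against as the whole cause. With SNPs listed in both tissues alone, 86.7% of 30 called genes (69.3% to 96.2%) and 83.1% of 59 (71.0% to 91.6%) were lower in brain. Low read numbers are argued against likewise, with 87.9% of 33 (71.8% to 96.6%) and 81.8% of 44 (67.3% to 91.8%) at 40 reads or more per SNP, and a difference between tissues in the fetuses stays open.

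The third pattern is that at SNPs seen both ways round the direction followed the base and not the parent. Mapping towards the reference genome is argued against as the whole cause, because the reference base was the higher one in 56.1% (48.4% to 63.7%) of 171 such SNPs. A difference carried by the whole allele of a gene, as a variant in a regulatory region could give, cannot be told apart from effects of single SNPs: of 1188 pairs with another SNP of the gene and fetus over 150 bases away, 91.2% lay on the same parental side (72.2% to 97.2%), an interval that includes the bound of 75%.

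With tissue labels swapped within fetuses, 1 of 100 splits, the real one, gave as many calls between brain and kidney (54, highest other 46) and 1 of 100 between brain and lung (77, highest other 65). This is the lowest rank that 100 splits can give. It argues against chance for the full counts, but does not tell which share of the single calls is real. Between kidney and lung 7 of 100 splits gave as many as the real 3 (highest other 5), and chance cannot be excluded. For the 1 gene called in share between restricted and control lungs, GOLGA3, 3 of 35 splits of the units gave at least 1 call (highest other 2), so chance cannot be excluded. In the other 17 diet comparisons the real split gave 0 calls, which all 35 of 35 splits reach. The highest other counts, in the order restricted minus control, overfed minus control and overfed minus restricted, were 1, 0 and 2 for share in brain and 3, 1 and 2 in kidney, with 1 and 3 for the last 2 contrasts in lung. For coverage they were 3, 0 and 2 in brain, 1, 2 and 1 in kidney, and 1, 1 and 2 in lung.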

How the results depend on the processing

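Leaving out SNPs heterozygous in 10 or more fetuses, the minimum of 40 reads, both bases seen as paternal, and SNPs listed in both tissues were chosen after seeing the data. No minimum or one of 20 reads changes nothing, because each listed SNP has over 20 reads, so these say nothing about stability. Depth limits what can be listed: a SNP under 20 reads has no value. For the moved results below, fewer genes are tested under the stricter settings, and otherwise the cause was not tested.

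Counts of genes biased by parent stayed within 1.5 times in 66 of 102 settings and results. In brain, kidney and lung, 318, 393 and 526 genes were called without SNPs heterozygous in 10 or more fetuses, 219, 284 and 415 with 40 reads, 306, 347 and 536 with at least 5 fetuses, 227, 263 and 402 by the exact sign-flip test, 313, 360 and 488 in control fetuses, and 101, 156 and 190 when genes with both bases seen were tested by themselves. With at least 2 fetuses kidney had 1197. Monoallelic genes numbered 313, 281 and 289 at a threshold of 80% or 20%, 12, 5 and 11 at 95% or 5%, 25, 8 and 17 by the sign-flip test, and 3, 1 and 1 with both bases, tested by themselves. They were 35 in brain and 10 in kidney with at least 5 fetuses, 43 in kidney with at least 2, 13 in kidney without SNPs heterozygous in 10 or more fetuses, and 21 in lung with 40 reads. ZFAT, not called, turned to a logit of 0.597 in brain and 0.0511 in lung against the median logit, which itself lay on the maternal side. Leaving out 1 fetus gave 483 to 561, 618 to 682 and 825 to 879 genes, and 53 to 65, 17 to 25 and 29 to 35 monoallelic genes.

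Tissue counts stayed within 1.5 times in 33 of 45. Between brain and kidney, brain and lung, and kidney and lung, 8, 12 and 1 genes were called without SNPs heterozygous in 10 or more fetuses. Brain against kidney and lung had 33 and 44 with 40 reads, 30 and 39 in control fetuses, and 4 and 19 from SNPs in both tissues without the widely heterozygous ones. Brain against kidney had 30 from SNPs in both tissues. Kidney against lung had 11 with precision weights and 5 with the fetus as a random effect. The fetus as a block changed the call of CDCA7L (adjusted p = 0.235). Leaving out 1 fetus gave 44 to 59, 57 to 77 and 2 to 5, with 5 without control replicate 6 or without overfed replicate 3. KIAA1644 between brain and lung was lost without control replicate 4 (adjusted p = 0.0892).

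Diet counts in share stayed as they were in 115 of 126. In brain, restricted minus control had 1 with precision weights and 1 with each fetus as a value, and overfed minus restricted 1 with 40 reads and 1 with precision weights. Kidney restricted minus control had 1 without SNPs heterozygous in 10 or more fetuses. In lung, restricted minus control had 0 from the deepest SNP, with 40 reads, with precision weights, with the replicate block and with the ram as a covariate, and overfed minus restricted had 1 from the deepest SNP. Over 25 alternatives GOLGA3 kept its lung call in 16, with adjusted p from 0.00832 to 0.875. Leaving out 1 library gave 0 to 2 in kidney restricted minus control (2 without control replicate 2, 1 without restricted replicate 1), 0 to 2 in lung restricted minus control (2 without restricted replicate 4), 0 to 1 in lung overfed minus control (1 without control replicate 1 or overfed replicate 1), 0 to 1 in lung overfed minus restricted (1 without overfed replicate 1 or restricted replicate 4), and 0 in the other 5. Coverage counts stayed in 96 of 99: 1 in kidney overfed minus control with the replicate block, and in lung overfed minus restricted 1 with scaling by total coverage and 1 with the ram. Leaving out 1 library gave 0 to 1 in lung overfed minus control and overfed minus restricted (1 without overfed replicate 1) and 0 elsewhere. Without scaling, the log2 differences of NETO2 in brain and ZFX in lung for overfed minus control, not called, turned to 0.13 and 0.0044. The replicate numbers pair nothing across diets: the median correlation across genes for equal numbers was 0.0804 in brain, -0.0876 in kidney and 0.0112 in lung, against -0.0465, 0.0244 and -0.0194 for other pairs. The reference share of summed reads was 45.1% in brain and 48.7% in kidney.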

Other observations

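The genes of this part, and the list of X genes that have a copy on the Y chromosome, were chosen after the values were seen, and the fetuses were not tested against each other on X.

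Among genes that kept their side in all 3 tissues with both bases seen, AHNAK, a large scaffold protein, was paternal at 83.9% ± 10.6 (n = 7) in brain, 81.4% ± 3.72 (n = 15) in kidney and 79.3% ± 4.49 (n = 15) in lung. TTC21B, a ciliary transport gene, was paternal at 82.2% ± 5.38 (n = 6), 81.7% ± 7.34 (n = 8) and 76.02% ± 2.53 (n = 6). PARG, which removes poly(ADP-ribose), was paternal at 82.8% ± 7.72 (n = 3), 80.02% ± 4.93 (n = 7) and 80.3% ± 7.99 (n = 12), and ADSSL1 at 76.2% ± 14.5 (n = 5), 77.6% ± 4.79 (n = 8) and 77.98% ± 3.25 (n = 8). In kidney each of these genes had fetuses that carried both bases, at different SNPs. Parent of origin was thus not separated from a difference carried by the whole allele.

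NPC1, a cholesterol transporter, was paternal at 95.1% ± 2.47 (n = 8) in brain and 72.5% ± 6.005 (n = 10) in lung from SNPs heterozygous in fewer than 10 fetuses.

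On chromosome X the fetuses differed in what was listed. In 8 fetuses (control 1 to 4, overfed 1 and restricted 1, 3 and 4), X SNPs were 0.673% to 1.03% of the heterozygous SNPs, 59.3% to 75.6% of their X entries lay in genes that have a copy on Y, such as USP9X and KDM6A, and the median paternal share of their libraries was 74.4% to 86.3%. In the other 7 fetuses, X SNPs were 1.25% to 2.48%, 0% to 3.44% of X entries lay in such genes, and the library medians were 17.5% to 76.1%, above 50% in the kidney of control fetus 6 (76.1%), the lung of overfed fetus 2 (74.3%) and the lung of restricted fetus 2 (76.1%). USP9X had 319 entries in 10 fetuses and KDM6A 171 in 9.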
